A study of Mus musculus with 2 samples.

How the data were processed

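MicroRNA-seq libraries were made from total RNA of C2C12 cells, a mouse myoblast line that grows as undifferentiated cells and fuses into myotubes when serum is withdrawn. Per the labels, the libraries hold RNA shorter than 30 nucleotides, and they are numbered as 2 biological replicates of 1 group. The labels also point to a protocol for adapter trimming. The labels name no treatment, time or culture stage, so no contrast between conditions exists. The replicate numbers mark separate biological samples per the labels, and no batch or date that could split them is given there.

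Each deposited table holds, for 2202 miRNA genes, whole-number read counts as the authors made them, in 3 columns for reads on either strand, reads on the strand of the gene and reads on the opposite strand. The remaining rows give unmapped reads, reads that mapped to several places, reads on no miRNA gene and ambiguous reads. These rows name no gene and stayed out of library totals and tests. They made up 49.7% of the reads in replicate 1 and 38.8% in replicate 2. The mm10 build and the GENCODE M21 annotation are named in the deposited readme files. The aligner and counter are not given in the sources used here. The row and column layout is that of the gene counts STAR can write, in which only reads with 1 place in the genome are counted, but no source used here names STAR. Multi-mapping reads have a row of their own with the same value in all 3 columns. If such reads were left out of the gene counts, genes with near-identical copies are understated. The counts are per hairpin gene and do not separate the 2 arms of a hairpin.

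All 2202 gene identifiers matched GENCODE M21 on mm10, which supplied symbols, positions, hairpin sequences and host genes. Of the matched genes, 1174 have a symbol that starts with Mir and most others are unnamed predictions. Host genes were taken as genes of other types that span the hairpin on its strand, and a hairpin counted as exonic where it overlapped any annotated exon. Hairpins that share a stretch of at least 20 bases with a non-overlapping miRNA gene were taken as near-identical copies.

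The same-strand column was used throughout, since it held 27661907 reads in replicate 1 and 15025315 in replicate 2 against 843574 and 244513 on the opposite strand. Levels are counts per 1e+06 reads of this total (CPM), given as mean ± SD of the 2 libraries. This SD includes the shift in the share of Mir21a between the totals, so it does not measure how stable a single gene was. A gene counted as detected at a CPM of at least 1 in both libraries. A count of 0 allows up to 3 counts, which is 0.108 CPM in replicate 1 and 0.2 CPM in replicate 2. Shares of single libraries carry exact (Clopper-Pearson) 95% intervals. Intervals and floors cover counting error only, since amplified reads without molecular identifiers are not independent molecules.

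The libraries were compared after trimmed-mean (TMM) scaling in edgeR 4.0.16 under R 4.3.3, which moved the log2 ratio of every gene by 0.90 against scaling by library totals. Each gene with at least 10 counts over both libraries was tested with a two-sided exact binomial test of its pair of counts, with Benjamini-Hochberg adjustment over 556 genes and a threshold of 0.05. Log2 ratios carry a prior count of 0.5 and a counting standard error. This test compares the 2 libraries, not conditions. The spread between replicates was taken as edgeR's common coefficient of variation. Correlations were taken over log2(CPM + 1) after scaling. Each of 15 gene lists was compared between the libraries through the percentile of its median log2 ratio among 10000 random lists of the same size, matched on mean expression in 10 bins, as a description without a p-value. Lists with under 3 tested genes got no percentile.

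The tests were run on simulated counts of the same 556 genes. With counting noise only, 67 of 100 genes raised 2-fold and 56 of 100 genes lowered to 0.5-fold were recovered. When other genes were changed, 6 unchanged genes were called (1.69%), and none of the 556 genes was called when nothing was changed. These runs of the binomial test held no spread between replicates beyond counting noise. They therefore do not show how many calls such a spread gives in the real libraries. A true coefficient of variation of 0.3 was estimated as 0.298.

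The gene lists, the rule for named genes, the tests and most alternatives were fixed before the data were examined. The coefficient of variation, the replicate agreement and the list shifts are descriptions. The rule named the 20 genes with the highest mean CPM, up to 3 highest members of each list, and the 4 largest TMM-scaled log2 ratios in each direction among genes with a mean CPM of at least 100 that passed the test. Of 202 list entries, 190 matched by symbol, 11 through RefSeq synonyms (GRCm38.p6), and 1, Mir124-1, was not matched. The alternatives were DESeq2 1.42.0 size factors, library totals, other count filters, counts of either strand, thinning of the deeper library and leaving out a replicate. Leaving out Mir21a from the comparison of the libraries and from the top 10 share, scaling by totals without it, and keeping only genes without a near-identical copy were added after the data had been seen. Other computations used Python 3.11.15 with scipy 1.17.1.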

Results

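Small RNA from the mouse myoblast line C2C12 was sequenced in 2 biological replicates of a single group, whose culture stage is not given. Replicate 1 held 55036610 reads, of which 50.3% were counted on the strand of a miRNA gene, and replicate 2 held 24569278 reads, of which 61.2% were counted. Reads that mapped to several places made up 33.4% of replicate 1 and 22.8% of replicate 2. Unmapped reads made up 12.8% and 12.7%, and reads on no miRNA gene 3.54% and 3.33%. The design has no second condition, so the data describe the miRNA repertoire of these cells and how closely the libraries matched.

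A single gene led the repertoire. Mir21a, a miRNA abundant in many proliferating and tumour cells, took 38.3% ± 21.5 of the counted reads (SD, n = 2), with 23.1% in replicate 1 and 53.5% in replicate 2. Mir22 followed at 66606 ± 8655 CPM, then Mir23a at 51955 ± 28454, Mir143 at 48683 ± 17906, Mirlet7i at 46712 ± 27975 and Mir31 at 29595 ± 2240 CPM (SD, n = 2 for each). Mir143 is known from smooth muscle and fibroblasts, and Mir31 from muscle satellite cells. The Mir23a hairpin shares a stretch of 20 bases with Mir23b, so the split of reads between them is uncertain. The 10 most abundant genes of each library held 69.6% ± 12.6 of its counts (SD, n = 2). Of the top 20 genes of each library, 18 were shared.

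The leading genes lay in different kinds of transcription unit. On mm10, the Mir21a hairpin spans positions 86584067 to 86584158 of chromosome 11 on the minus strand and overlaps an annotated exon of the protein-coding gene Vmp1. Its 92-base sequence in the annotation is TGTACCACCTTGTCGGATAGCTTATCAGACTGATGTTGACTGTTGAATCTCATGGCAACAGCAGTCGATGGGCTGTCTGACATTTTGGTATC. Mir22 (chromosome 11, 75463716 to 75463810, plus strand) overlaps an exon of its host transcript Mir22hg and an annotated exon of Tlcd2. Mir140 (chromosome 8, 107551244 to 107551313, plus strand), known from cartilage, overlaps an annotated exon of Wwp2 and reached 17856 ± 3750 CPM. Mirlet7g (chromosome 9, 106178840 to 106178927, plus strand) lies in an intron of Wdr82. Mir378a (chromosome 18, 61397835 to 61397900, minus strand) lies in an intron of Ppargc1b, a regulator of mitochondrial genes, and reached 9094 ± 3637 CPM. It overlaps Gm25301 on the other strand, and counted without strand both genes have 0 reads. Mir23a (chromosome 8, 84208518 to 84208592, plus strand) and Mir143 (chromosome 18, 61649196 to 61649258, minus strand) had no annotated host gene on their strand.

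**Figure D1:**
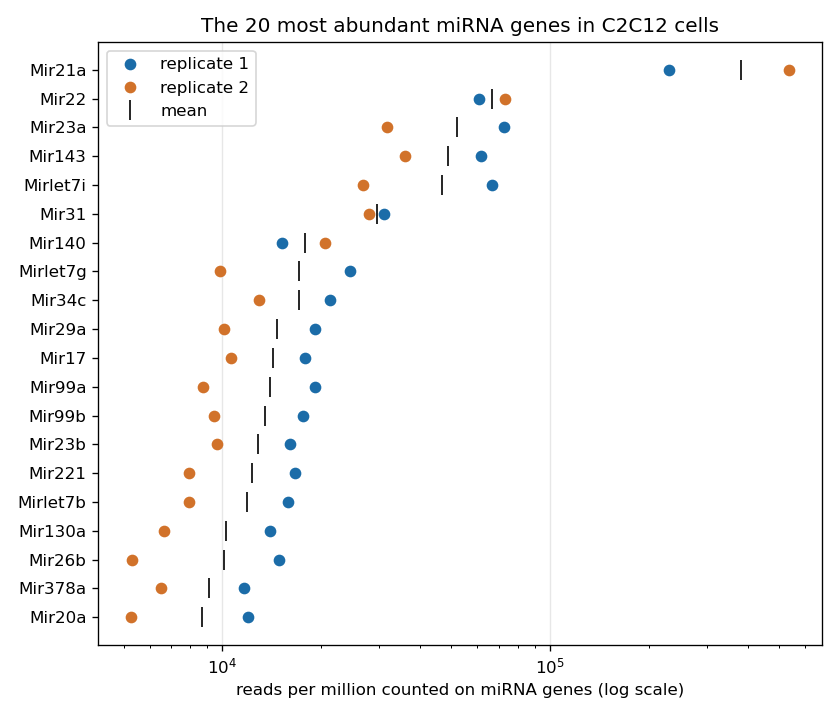
CPM of counted miRNA reads (log scale) for the 20 genes with the highest mean, with 1 point per replicate and a bar for the mean. Mir21a stands above all others in both libraries, and Mir21a, Mir22 and Mir140 are the genes of the plot whose share was higher in replicate 2.

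Across the annotation, 320 of 2202 genes were detected at a CPM of at least 1 in both libraries. Of these, 192 reached a CPM of 10, 123 a CPM of 100 and 62 a CPM of 1000 in both. No read was counted in either library on 1398 genes. The deeper replicate 1 had 398 genes at a CPM of at least 1 and replicate 2 had 323. When replicate 1 was thinned to the depth of replicate 2, it still had 388. The thinning matched library totals only, and before it reads on genes other than Mir21a numbered 21283877 in replicate 1 and 6984408 in replicate 2. It therefore cannot separate depth from the larger share of Mir21a in replicate 2.

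The muscle-specific miRNAs were represented almost entirely by Mir206, which is specific to skeletal muscle and is known to rise as myoblasts differentiate. Mir206 had 2559 CPM in replicate 1 and 1028 CPM in replicate 2, a mean of 1794 ± 1082 (SD, n = 2). Its neighbour Mir133b, whose hairpin shares a stretch of at least 20 bases with another miRNA gene, had 88.0 and 20.4 CPM. Of the 12 genes on the muscle list, 4 were detected in both libraries, the other 2 being Mir1b at 3.65 ± 1.12 CPM and Mir486 at 2.54 ± 1.99 CPM (SD, n = 2). No read was counted on Mir1a-1, Mir133a-1, Mir133a-2 or the cardiac Mir208a in either library. The Mir1a-1 and Mir1a-2 hairpins share a stretch of 28 bases and the Mir133a-1 and Mir133a-2 hairpins one of 31 bases, so reads of these miRNAs fit more than 1 place and a count of 0 sets no limit on them. The list took 0.186% ± 0.113 of the counts.

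The X-linked cluster of Mir322 and Mir503, known for a role in cell cycle exit during myogenesis, was expressed, with 7 of 7 genes detected. Mir322 led with 7066 ± 3016 CPM, followed by Mir351 with 620 ± 201 and Mir503 with 188 ± 52.2 CPM (SD, n = 2). All 17 genes on the list of other miRNAs reported to rise in myoblast differentiation were detected as well, and together took 3.64% ± 1.40 of the counts. Its highest members were Mir29a at 14639 ± 6380 CPM, Mir378a at 9094 ± 3637 CPM and Mir27b at 5062 ± 677 CPM. Most genes of this list, among them Mir378a and Mir27b, have near-identical copies, so their levels are uncertain. Mir29a, a repressor of collagen genes, is 1 of the 20 most abundant genes.

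Clusters tied to proliferation were abundant. Of the 15 genes of the clusters that hold Mir17, Mir106a and Mir106b, 12 were detected and took 3.62% ± 1.51 of the counts. Mir17 reached 14256 ± 5157 CPM, Mir20a 8649 ± 4767 CPM and Mir93 4092 ± 1928 CPM (SD, n = 2). The X-linked cluster of Mir106a was low, with Mir106a at 7.23 and 3.33 CPM in the 2 libraries, no read on Mir363, and most reads on Mir92-2 at 44.2 and 28.2 CPM. Mir92-2 and Mir19b-2 of this cluster have near-identical copies, so their levels are uncertain. The let-7 family, known to rise as cells differentiate, took 9.28% ± 5.26 of the counts with 13 of 14 genes detected, led by Mirlet7i, Mirlet7g at 17189 ± 10364 CPM and Mirlet7b at 11880 ± 5566 CPM. The miR-232724 clusters took 8.04% ± 3.66, with Mir23a, Mir23b at 12870 ± 4560 CPM and Mir27a at 7851 ± 1635 CPM in the lead. All genes of these clusters have near-identical copies, so their levels are uncertain too.

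The list of fibroblast and mesenchymal miRNAs held 57.3% ± 18.2 of the counts, with 15 of 17 genes detected. Mir21a alone made up most of it. Mir22 and Mir143 came next, and Mir99a stood at 13987 ± 7394 CPM and Mir221 at 12318 ± 6206 CPM (SD, n = 2).

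The imprinted Dlk1-Dio3 miRNA cluster on chromosome 12, which is active in fetal muscle and in many stem cells, was close to silent. None of its 57 genes reached a CPM of 1 in both libraries, and 36 had no read in either. The whole cluster had 84 reads in replicate 1 and 47 in replicate 2. This is 3.04 CPM, or 0.000304% (exact 95% interval 0.000242 to 0.000376), and 3.13 CPM, or 0.000313% (0.00023 to 0.000416). Its highest gene, Mir411, had 0.434 and 0.333 CPM.

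Markers of other cell types were low with a few exceptions. Of the blood cell list, 4 of 9 genes were detected, with Mir155, which is also expressed outside the blood lineage, at 6684 ± 2593 CPM. Mir142, which is largely restricted to blood cells, had 168 ± 65.6 CPM and Mir146 11.4 ± 0.128 CPM (SD, n = 2). The endothelial Mir126a had 174 ± 55.8 CPM. Among neural genes 4 of 14 were detected, with Mir132 at 420 ± 146 CPM, its neighbour Mir212 at 96.7 ± 53.1 and Mir128-1 at 17.8 ± 4.99 CPM. The 3 Mir9 and 3 Mir124a genes had at most 2 reads, but each shares a stretch of at least 20 bases with its copies, so such counts set no limit on these neural miRNAs. The liver and gut list reached 110 ± 1.6 CPM in sum, most of it from Mir192 at 64.0 ± 9.16 CPM and Mir194-2 at 43.2 ± 13.1 CPM, while the hepatocyte gene Mir122 had 2.58 ± 1.87 CPM. Endocrine genes were represented by Mir7-1 at 164 ± 20.5 CPM, with 3 of 4 genes detected. Mir7-1, Mir128-1, Mir194-2 and Mir146 also share a stretch of at least 20 bases with another miRNA gene, so their levels are uncertain. Epithelial genes summed to 21.6 ± 3.79 CPM, led by Mir205 at 9.02 ± 0.332 and Mir200c at 6.78 ± 2.43 CPM. Of the 14 pluripotent cell genes none was detected in both libraries, and they had 25 reads in replicate 1 and 8 in replicate 2.

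**Figure D2:**
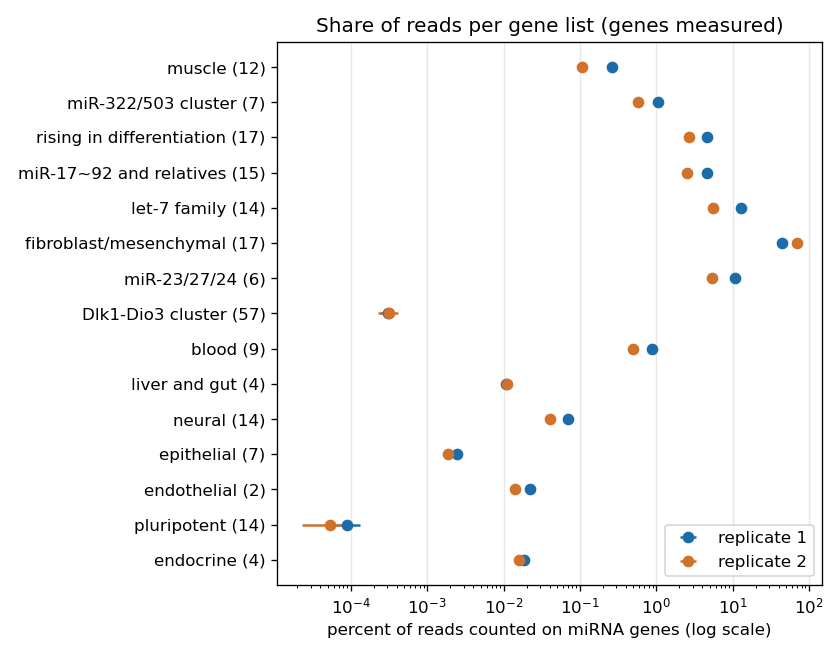
Percent of counted miRNA reads (log scale) on each gene list, with the number of measured genes in brackets, 1 point per replicate and exact 95% counting intervals. Fibroblast and mesenchymal genes took 44.5% of replicate 1 and 70.2% of replicate 2, while the Dlk1-Dio3 and pluripotent lists lie below 0.001% in both.

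The replicates were compared to measure how far the libraries differed after TMM scaling. The SDs of the levels above are per library total, of which Mir21a took 23.1% and 53.5%, and so hold this shift as well. Mir322, at 7066 ± 3016 CPM, had a TMM-scaled ratio of replicate 2 over replicate 1 of 0.999. For Mir146, at 11.4 ± 0.128 CPM, this ratio was 1.84. Across the 556 genes with at least 10 counts, log2 CPM correlated with Pearson's r = 0.99 and Spearman's rho = 0.958 between the libraries. This is a correlation across genes, which are not independent replicates. The median absolute log2 ratio was 0.33, or 1.26-fold, over the 210 genes with a mean CPM of at least 10. The common coefficient of variation between the replicates was 34.3% (0.343, with a range of 0.29 to 0.399 in 95% of gene resamples). With library totals in place of TMM scaling, as in the CPM levels, it was 0.492.

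The libraries differed by more than counting noise, a yardstick that any separately prepared libraries of this depth may exceed. The exact binomial test with Benjamini-Hochberg adjustment called 231 of 556 genes, 137 higher and 94 lower in replicate 2. The split rests on the scaling, since DESeq2 size factors gave 124 higher and 107 lower, and library totals gave 26 higher and 304 lower. Of the TMM calls, 62 differed at least 2-fold, 43 higher and 19 lower. Among the 210 genes with a mean CPM of at least 10, 27 were called and differed at least 2-fold. By library totals instead of TMM, 170 genes were called at least 2-fold apart.

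The largest called differences toward replicate 2 among genes with a mean CPM of at least 100 were in Snord43, Mir21a, Mir342 and Mir452. Snord43, an entry of the miRNA annotation in an intron of Rpl3 that carries the name of a small nucleolar RNA, had 1537 and 9487 reads, a log2 ratio of 4.40 (counting SE 0.04). Mir21a had a log2 ratio of 2.11 after TMM scaling, or 4.32-fold. This was the third highest among 210 genes and 3.02 times the SD that the common coefficient of variation implies for a ratio of 2 replicates, 0.70. The observed SD of the log2 ratios over these 210 genes was larger, at 0.84. Mir342 was 3.02-fold and Mir452 2.72-fold higher. Mir22 and Mir140 were also higher, by 2.24-fold and 2.51-fold. Snord43, Mir21a, Mir22 and Mir140 were higher in replicate 2 under all 3 scalings. By library totals Mir342 was also higher there, with 297 CPM in replicate 1 and 482 in replicate 2. So was Mir452, with 82.7 and 121 CPM. The largest called differences toward replicate 1 were in Mir185, at 7.15-fold with 10851 and 442 reads, Mir296 at 2.30-fold, Mir33 at 1.69-fold and Mir467c at 1.62-fold.

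Many other abundant genes differed little. Mir322 had a log2 ratio of 0.00 (adjusted p = 0.945, exact binomial test, counting SE 0.006), and Mir99b one of 0.00 (adjusted p = 0.67, exact binomial test, counting SE 0.0044). Mir29a differed by 0.02 toward replicate 1, which the depth resolved (adjusted p = 1.29e-06, exact binomial test). Such small ratios depend on the scaling. With DESeq2 size factors Mir322 and Mir99b had log2 ratios of -0.06 and -0.07 and passed the test.

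**Figure D3:**
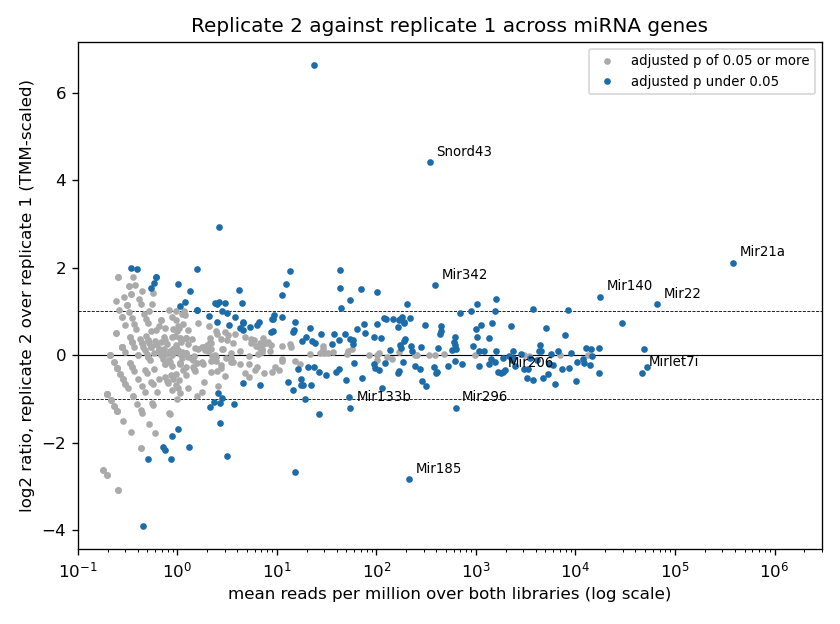
Log2 ratio of replicate 2 over replicate 1 after TMM scaling against mean CPM (log scale), for 556 genes with at least 10 counts. Blue points passed the exact binomial test with adjustment, dashed lines mark 2-fold, and Mir21a, Snord43 and Mir185 lie outside the band of other abundant genes.

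With TMM, the median of no gene list with at least 3 tested genes lay outside the central 95% of matched random lists. Over all tested genes, 231 of 556 (41.5%) were called, 137 higher and 94 lower in replicate 2. Genes with more reads pass this test more readily, so the number of calls in a list also reflects how abundant its genes are. Mir206 was 1.34-fold and Mir133b 2.31-fold higher in replicate 1 and both passed the test, and 3 of the 7 tested muscle genes were called lower in replicate 2 and none higher, also adjusted over the list alone. The median of the muscle list lay at the 34.1th percentile of matched random lists. For genes reported to rise in differentiation, 10 of 17 were called higher and 3 lower in replicate 2 (15 called adjusted over the list alone), with the median at the 89.8th percentile. The let-7 family had 4 called higher and 8 called lower of 14 (12 called adjusted over the list alone), at the 9.04th percentile. The mesenchymal list had 10 called higher and 4 called lower of 17 (14 called adjusted over the list alone), at the 96.6th percentile. By library totals the differentiation list had 1 called higher and 12 lower, the let-7 family 1 and 12, and the mesenchymal list 2 and 14, with percentiles as above. The 6 tested genes of the miR-232724 clusters had 4 called higher and 2 lower, and the 14 of the Mir17 group 5 higher and 2 lower. The blood list had 3 higher, the liver, epithelial and endocrine lists 2 each, the endothelial list 1, the Mir322 cluster 3 higher and 1 lower, the neural list 2 each way, and the Dlk1-Dio3 and pluripotent lists none. Adjusted over the list alone, the Mir322 cluster had 5 calls and the others of these lists as many as over all genes. By library totals the lower calls numbered 11 in the Mir17 group, 6 in the Mir322 cluster, 5 in the miR-232724 clusters, 4 in the neural list, 3 each in the blood and liver lists, 2 in the endothelial list and 1 each in the epithelial, endocrine and pluripotent lists, with 1 higher call, in the liver list. With DESeq2 size factors the Mir322 cluster had 3 calls and the Mir17 group 4 calls in each direction, the neural list 1 higher and 2 lower, and the epithelial list 1 higher. Percentiles of the lists not given above lay between 24.8 and 94.6.

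Many genes with a near-identical copy elsewhere had low counts beside their cluster neighbours, though not all, since Mir92-1 at 3046 CPM lay above Mir18 at 2236 CPM. Mir23a at 51955 CPM, Mir23b at 12870 CPM and Mir378a at 9094 CPM also have such a copy. Genes with one took 15.1% of the counts in replicate 1 and 7.84% in replicate 2. As examples of lower counts, Mirlet7c-1 had 112 CPM on average beside Mir99a at 13987 CPM. Mir29b-1 had 177 CPM beside Mir29a at 14639 CPM, and Mir199a-2 had 49.0 CPM beside Mir214 at 3477 CPM. Copies of 1 miRNA also differed, as with Mir24-2 at 2476 ± 1311 CPM and Mir24-1 at 147 ± 5.84 CPM (SD, n = 2). Their hairpins share the stretch CACTGGCTCAGTTCAGCAGGAACAGGAG, so how reads were split between them is uncertain. The same holds for the levels of Mir16-1, Mir16-2, Mir92-1, Mir133b and the let-7a, let-7c and let-7f genes.

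**Figure D4:**
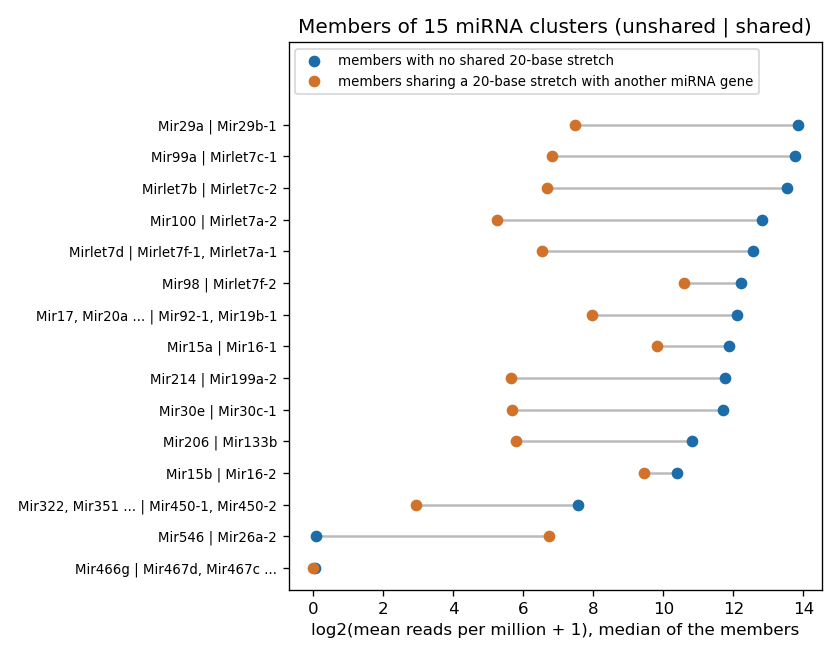
Median log2(mean CPM + 1) of cluster members that share a stretch of 20 bases with another miRNA gene (orange) and of those that do not (blue), for 15 clusters within 10000 bases on 1 strand. The median with a shared stretch lies lower in 14 of the 15 clusters, by only 0.047 at the floor in the cluster of Mir467d, Mir467c and Mir467e beside Mir466g, and higher for Mir26a-2 beside Mir546.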

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

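The tests on near-identical genes, on opposite-strand reads, on multi-mapping reads, on GC content in its present form and on the coefficient of variation without Mir21a were chosen after the result had been seen. The share of Mir21a had also been seen before its other tests were chosen, but not what those tests measure.

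The multi-mapping row and the opposite-strand column, which were not used for the miRNA levels, held values far above the limit of a count of 0. Multi-mapping reads numbered 18382947 in replicate 1 and 5599235 in replicate 2. Reads on the strand opposite to an annotated miRNA gene numbered 843574 in replicate 1 and 244513 in replicate 2. No control libraries were analysed here.

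The multi-mapping reads bear on the low counts of genes with near-identical copies. In 15 clusters with a member of at least 100 CPM, the median of the members that share a stretch of 20 bases with another miRNA gene lay below that of the other members in 14, with a median log2 difference of -5.02 and a mean of -3.85 (two-sided exact sign-flip test of the mean, p = 0.00269; medians -4.52 over 14 clusters, exact p = 0.00708, and -5.19 over 16, exact p = 0.00162, with stretches of 18 and 22 bases). Of the 14, the cluster of Mir467d differed by only -0.047 at the floor while its highest members share a stretch, and comparing the highest member of each kind left 13 of 15 clusters lower (mean -3.39, exact p = 0.0248). The clusters are not independent, since let-7 copies recur in several and Mir16-1 and Mir16-2 are copies of each other. The p-values may therefore be too small. Neighbours without a shared stretch also differed, as Mir143 at 48683 and Mir145a at 1446 CPM. Some differed by more than the median gap above, as Mir17 at 14256 and Mir19a at 21.6 CPM. Others lay closer, as Mir191 at 2340 and Mir425 at 1572 CPM. How often such neighbours differ as much was not tested. The lower counts are what reads left out because they match several places would give. The sign-flip test cannot weigh this against low transcription, since a cluster entered through any member of at least 100 CPM. Clusters whose members all share a stretch, such as that of Mir23a, Mir27a and Mir24-2, gave no comparison. In the clusters compared, low transcription of a transcript shared by the neighbours would not by itself give such gaps. Whether the neighbours share a transcript was not tested. Differences in processing or stability of single hairpins remain open and were not tested.

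The reads on the opposite strand lay almost wholly on genes that overlap another miRNA gene, 99.9% of them in each library (the lower value is 99.947%). The reads opposite to Gm25301 numbered 322706 in replicate 1, as did the reads on Mir378a, which overlaps it. A set of reads entered in both columns would give this. Outside such overlaps 429 and 129 reads remained, of which 143 and 34 lay opposite to Mir708.

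Mir21a took 23.1% of the counts in replicate 1 and 53.5% in replicate 2. With library totals the coefficient of variation fell from 0.492 to 0.335 without Mir21a, against 0.343 with TMM. Its dominance of the total thus accounts for the wider spread by library totals. With TMM, which already sets it aside, 41.5% of 556 genes differed with Mir21a and 41.4% of 555 genes without it. Since TMM had already set Mir21a aside, leaving it out could hardly move this percentage. The comparison therefore cannot decide whether its dominance bears on the differences that remain after TMM scaling. A linear trend with hairpin GC content is argued against, since the trend over the other 209 genes adds 0.0034 (95% of resamples -0.072 to 0.075) to the Mir21a log2 ratio of 2.11. Loss of Mir21a reads to multi-mapping in replicate 1 is argued against as well: per read on other genes, multi-mapping reads numbered 0.864 and 0.802 in the 2 libraries, an excess of 7.28% of the Mir21a reads that replicate 1 lacked. A difference in library preparation that acts on RNA sequence may contribute and cannot be told apart from one in transcription between the cultures, as 55 pairs of unlinked genes with a shared stretch of 14 bases differed by 0.816 times the median of permuted pairs (one-sided permutation p = 0.182), 72 pairs of cluster neighbours with no shared stretch of 12 bases, some of them members of the same miRNA family such as Mir29a and Mir29b-1, differed by 0.973 times the median of permuted pairs (one-sided permutation p = 0.443) and only 2 libraries were analysed.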

How the results depend on the processing

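Leaving out Mir21a from the comparison of the libraries and from the top 10 share, scaling by totals without it, and keeping only genes without a near-identical copy were chosen after seeing the data. All other alternatives were planned. No test has a group contrast, and a comparison of the libraries has no value without a replicate. Of the values behind the main results, 161 stayed within their limits under an alternative and 33 moved. Limits were 1.5 times for counts, 1 SD for shares, the 95% range of gene resamples for agreement, and the central 95% of random lists for list shifts. With 2 replicates, a share from 1 of them always lies within 1 SD of their mean, and a scaling factor common to all genes barely moves a percentile, so these settings say nothing about stability. Where an alternative's construction does not show the cause of a move, the cause was not tested. Detected genes numbered 320, and 192 with a CPM of 10 or 663 with a single count in both libraries, and leaving out a replicate gave 323 to 398. The top 10 share was 60.6 to 78.5% with 1 replicate left out and 53.5% without Mir21a. Library totals in place of TMM raised the genes at least 2-fold apart from 62 to 170, the median absolute log2 ratio to 0.86 and the coefficient of variation to 0.492, and gave 26 higher and 304 lower against 137 and 94. With only the 138 genes at a CPM of 100, 127 were called, 12 of them at least 2-fold apart, and Pearson's r was 0.963. Without a count filter Spearman's rho was 0.94, the median absolute log2 ratio 0.57, and the Dlk1-Dio3 list moved to the 98.2th percentile, over 21 genes of which 5 have at least 10 counts. Without Mir21a in the total, the shares became 1.30% for the Mir322 cluster, 5.86% for the differentiation list, 5.79% for the miR-17~92 group, 31.9% for mesenchymal genes, 12.8% for miR-232724, 0.000534% for Dlk1-Dio3, 1.10% for blood, 0.0191% for liver, 0.089% for neural, 0.00362% for epithelial, 0.0294% for endothelial, 0.000116% for pluripotent and 0.0291% for endocrine genes. Among genes without a near-identical copy the shares were 2.10% for differentiation, 0 for miR-232724, whose genes all have one, 0.000284% for Dlk1-Dio3, 0.00758% for liver and 0.000254% for endocrine genes. With counts of either strand, where reads on overlapping genes are set aside as ambiguous, they were 0.000261% for Dlk1-Dio3, 0.0113% for liver and 3.38e-06% for endothelial genes, since Mir126a and Mir126b overlap. Among the genes picked by the rule for named genes, the called log2 ratios that changed sign under library totals were those of Mir143 (-0.77), Mir31 (-0.15), Mir34c (-0.73), Mir17 (-0.75), Mir23b (-0.74), Mir378a (-0.84), Mir351 (-0.67), Mir503 (-0.57), Mir27b (-0.27), Mir27a (-0.43), Mir155 (-0.81), Mir146 (-0.021), Mir192 (-0.29), Mir132 (-0.73), Mir128-1 (-0.58), Mir205 (-0.072), Mir141 (-0.15), Mir126a (-0.67), Mir7-1 (-0.26) and Mir7-2 (-0.21). Other genes mentioned in the text, such as Mir24-1, also changed sign. Of these genes, Mir378a alone also did with DESeq2 size factors (-0.0032). Those of Mir21a, Mir22, Mir140, Mir342, Mir452, Snord43 and Mir185 kept their sign under library totals. Depth limits the ratios of the Dlk1-Dio3, pluripotent and other genes with only a few reads.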

Other observations

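The test in this part was chosen after the levels of Mir206 and Mir133b had been seen, and Gm22133 and Mir3074-1 were chosen after their values were seen. The lower Mir206 and Mir133b of replicate 2 raise the hypothesis that replicate 1 was further along in muscle differentiation. It would need that the muscle list and the differentiation list both lie under the 2.5th percentile of matched random lists in replicate 2. They lay at the 34.1th and 89.8th percentile, which leaves the hypothesis open, since neither lies outside the central 95% and the muscle median is over members that went both ways, some with few reads. The 3 muscle genes called against counting noise were lower in replicate 2, but Mir206 and its neighbour Mir133b prompted the hypothesis, and the log2 ratios of -0.42 for Mir206, -0.87 for Mir486 and -1.21 for Mir133b stand against an SD of 0.70 that the replicate coefficient of variation implies.

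The largest ratio among genes with a mean CPM of at least 10 belonged to Gm22133, a predicted miRNA gene that overlaps an exon of Ftl1, a ferritin gene (chromosome 7, 45458089 to 45458197, minus strand). It had 24 reads in replicate 1 and 703 in replicate 2, a TMM-scaled ratio of 98.5. Snord43, the next, is also not a canonical miRNA gene. Mir3074-1, which lies opposite to Mir24-1, went the other way, with 779 and 35 reads. Mir24-1 itself was 1.76-fold higher in replicate 2 after TMM scaling, but by library totals it had 151 CPM in replicate 1 and 142 CPM in replicate 2. Mir185, in an intron of Tango2, had 392 CPM in replicate 1 and 29.4 CPM in replicate 2.

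The unequal shares of multi-mapping reads, 33.4% and 22.8% of all reads, came close together once Mir21a was taken out of the reference, at 0.864 and 0.802 per read on other miRNA genes. Unmapped reads per read on other genes were 0.331 in replicate 1 and 0.448 in replicate 2.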
